A study of Mus musculus with 2 samples.

How the data were processed

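Gene expression was measured by mRNA sequencing in lenses of C57BL/6 mice at postnatal day 60. The series holds 2 libraries, 1 per genotype. The library called CKO below came from mice carrying both floxed copies of Msx2 and the Le-Cre transgene, which drives Cre recombinase in the lens and other surface-ectoderm tissues of the eye. The library called WT came from mice with the same floxed alleles and no Cre, so the presence of Cre differs between the libraries along with the loss of Msx2. Whether a library was made from 1 animal or from several pooled animals is not given in the sources used here.

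The submitters' processing notes name STAR 2.5.1b, HTSeq 0.6.0 and DESeq2 1.10.1, without saying what each was used for. The genome build and annotation are not given in the sources used here. The deposited table gives FPKM (fragments per kilobase of gene, scaled to library size) for 21673 genes in each library, with gene length, coordinates and gene type. That the values are FPKM was inferred from the values themselves, because multiplying each by its gene length gave whole multiples of a single step in each library. Taking that step as 1 read, 100% of the values came out whole within 0.001 of a read. The recovered reads summed to 17165504 in CKO and 20784737 in WT. Whether such a read is a single read or a pair was not settled.

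The step also shows what the deposited FPKM values were scaled to. It corresponds to an effective library of 23369238 reads in CKO and 15267100 in WT, which is 1.36 and 0.735 times the recovered totals. Normalization factors by the trimmed mean of M-values, computed here from the recovered reads with 30% of the log ratios and 5% of the mean levels trimmed at each end, were also 1.36 and 0.735. The values are therefore scaled for composition, which matters in lens, where a few crystallin genes take a large share of all reads. The table lists genes with 2 reads or more over both libraries.

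Gene identifiers were compared with GENCODE release M21 of the mouse assembly GRCm38. Of the identifiers, 21566 were found there (99.5%). All of these lay on the same chromosome, 99.98% overlapped the annotated gene, and 85.9% had the identical start. Coordinates below are those of the deposited table, on GRCm38 by this match. Gene symbols are those of the table.

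The design fixed before the data were examined assumed read counts. As the table holds FPKM, the rule it gave for normalized values was used, and the count rule was run on the recovered reads as an alternative. A gene was measured if its mean FPKM over both libraries was 1 or more. The log2 ratio was taken as CKO over WT after adding 1 to each FPKM, which understates the ratio of genes at low levels. A gene passed the size rule if that ratio reached 2-fold in either direction. With 1 library per genotype there is no replicate check, no p-value across genes was computed, and every difference describes these 2 libraries.

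Folds in the text are plain ratios of FPKM. Each has an exact (Clopper-Pearson, conditional binomial) 95% interval from the recovered reads. Shares of reads have exact binomial (Clopper-Pearson) 95% intervals. These intervals cover counting error only, not differences between animals or library preparations. A gene with 0 reads in a library was compared with a floor of 3 reads there, or 0.175 CPM in CKO and 0.144 in WT. That fold leaves out counting error in the other library, so the lower limit of the exact interval is given with it.

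Before the data were examined, 28 gene lists were fixed. Of these, 20 covered lens genes and pathways: crystallins, fibre cell genes, epithelial cell genes, lens transcription factors, apoptosis, inflammasome and pyroptosis, mitotic cell cycle, G1 regulators and CDK inhibitors, extracellular matrix and epithelial-mesenchymal transition (EMT), lens capsule basement membrane, BMP, WNT and FGF pathways, glutathione and antioxidant genes, unfolded protein and heat shock genes, cholesterol synthesis, interferon response, immediate early genes, mitochondrially encoded genes and ribosomal proteins. The other 8 held markers of cells that a dissected lens could carry: photoreceptors, inner retina and glia, pigment epithelium with iris and ciliary body, cornea and conjunctiva, leukocytes, endothelium, erythroid cells and skeletal muscle. For each list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size, drawn from the same 20 bins of mean level. A list stood apart below percentile 2.5 or above 97.5. As adding 1 FPKM makes a change of scaling move genes unevenly, positions were also computed under the other scalings, a choice made after the data were seen. After the data were seen, 4 lists were added for the closing section: further retinal neuron genes, further inner retina interneuron genes, ATF4 target genes and reactive glia genes.

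The genes named were chosen by a rule fixed in advance. It takes Msx2, Msx1, Pax6 and Foxe3, then the 10 highest and 10 lowest log2 ratios among genes past the size rule with a mean FPKM of 5 or more. From each list it takes up to 4 members past the rule with the largest ratios, or the 2 most abundant where none passed, and it adds the 5 most abundant genes in WT. Members of a list after the first 2 may be left out where counts are given. Genes named outside this rule are said to be so. Of the genes the rule takes, 1 is not reported here.

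Alternatives were median-of-ratios scaling, library totals, library totals without crystallins, other minimums, added reads or pseudocounts, a fold of 4, intervals wholly beyond 2-fold, unmatched random lists, means in place of medians, and lists without shared members. The authors' normalized values, foreseen as an alternative to counts, are the main values here. In simulated libraries of 21673 genes made for the CKO and WT comparison, 200 genes with a mean FPKM of 5 or more were changed. Among these the size rule recovered 100% of genes changed 4-fold and 99.0% of those changed 3-fold. Recovery of measured genes below 5 FPKM, where adding 1 FPKM understates ratios more, was not simulated. Of 10809 measured unchanged genes 41 passed the rule from counting noise alone. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No column of values per sample was left unused.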

Results

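Lens transcriptomes were compared between Msx2 conditional knockout mice (CKO) and floxed mice without Cre (WT) at postnatal day 60, with 1 library per genotype. The comparison asks which lens genes differ when Msx2, a homeobox transcription factor, is removed by Le-Cre. Reads assigned to genes numbered 17165504 in CKO and 20784737 in WT, and 10757 genes had a mean FPKM of 1 or more. As neither genotype was replicated, no difference below has been set against variation between animals.

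Msx2 was almost absent from the CKO library, at 0.0392 FPKM (3 reads) against 6.21 FPKM (311 reads) in WT. Its level was 159-fold lower (95% counting interval 53.8 to 774), and its log2 ratio of FPKM + 1 fell by 2.80, or by 5.50 with a pseudocount of 0.1. Msx2 (ENSMUSG00000021469) lies on the minus strand of chromosome 13 from 53466884 to 53473074 on GRCm38, and its protein-coding transcript has 2 exons. The exon flanked by loxP sites is not given in the sources used here, and the reads were counted over the whole gene. The related gene Msx1 was at 4.17 FPKM in CKO and 3.32 in WT, a log2 ratio of 0.26 that did not pass the size rule. Pax6, a transcription factor of eye development, was at 16.1 and 21.6 FPKM. Foxe3, a transcription factor of the lens epithelium, was at 63.0 and 116 FPKM. Its log2 ratio of -0.87 missed the size rule, as did that of Pax6, -0.41. Under library totals alone the log2 ratios of Msx1, Pax6 and Foxe3 were 0.96, 0.44 and 0.0058.

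In the CKO library, genes of the lens fibre programme were lower, and genes of retinal photoreceptors and of leukocytes were higher. By the size rule 627 genes were higher and 315 lower in CKO, while 9815 (91.2%) lay within 2-fold. Among protein-coding genes 563 were higher and 204 lower. The 10 highest ratios included those of Lypd2, Rcvrn, Gnat1, Xist, Cck, Lcn2, Nrl, Prph2 and Gnb3. Of these Gnat1 encodes rod transducin, Rcvrn the calcium-binding protein recoverin, Nrl a transcription factor of rods, Prph2 an outer-segment protein and Gnb3 a cone transducin subunit. Lypd2 was at 166 FPKM against 0.193, 860-fold higher (238 to 7106), on 2633 and 2 reads. Cck, which encodes cholecystokinin, was 76.4-fold higher (36.9 to 191), and Lcn2, which encodes the iron-siderophore carrier lipocalin 2, was 149-fold higher (78.2 to 326). The 10 lowest ratios belonged to Cryga, Rpl34-ps1, Gm4152, Rn7sk, Eif2s3y, Cryge, Plekha4, Igkj3, Crygf and BC048679. Plekha4 was 10.9-fold lower (9.88 to 12.0), BC048679 11.2-fold lower (7.78 to 16.5) and Rn7sk, the gene of the 7SK RNA, 38.6-fold lower (19.98 to 85.5). Igkj3 rested on 1 read in CKO and 10 in WT.

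The balance of higher and lower genes depended on how the libraries were scaled. With the deposited scaling 66.6% of the genes past the size rule were higher in CKO. Scaling to library totals alone moved the median log2 ratio of the measured genes up by 0.70, and gave 2234 higher and 73 lower genes (96.8% higher). Scaling to library totals without the crystallins moved it up by 0.23, and gave 1381 higher and 343 lower (80.1% higher). Among the 95 genes named by the rule, 85 passed the size rule. None of these could change sign, because the scalings shift log2 ratios by at most 0.89, less than 2-fold. Counts of such genes that stay below 0 hold by construction for the same reason. Under library totals alone 5 named genes that did not pass changed sign, Pax6 and Foxe3 among them. Under that scaling 20 of the 85, all lower in CKO, came within 2-fold. These were Cryaa, Crybb2, Cryba1, Bfsp1, Gja1, Npnt, Hsf4, Col4a1, Col4a2, Col4a3, Hspg2, Smad1, Fzd1, Fas, Gadd45a, Hmox1, Gclc, Dhcr7, Car14 and Pvalb, with log2 ratios from -0.83 for Car14 to -0.18 for Crybb2. Of them 5 (Hsf4, Gadd45a, Col4a3, Dhcr7 and Crybb2) also did so under totals without crystallins. Under median-of-ratios scaling 1 gene did, Atf4.

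**Figure D1:**
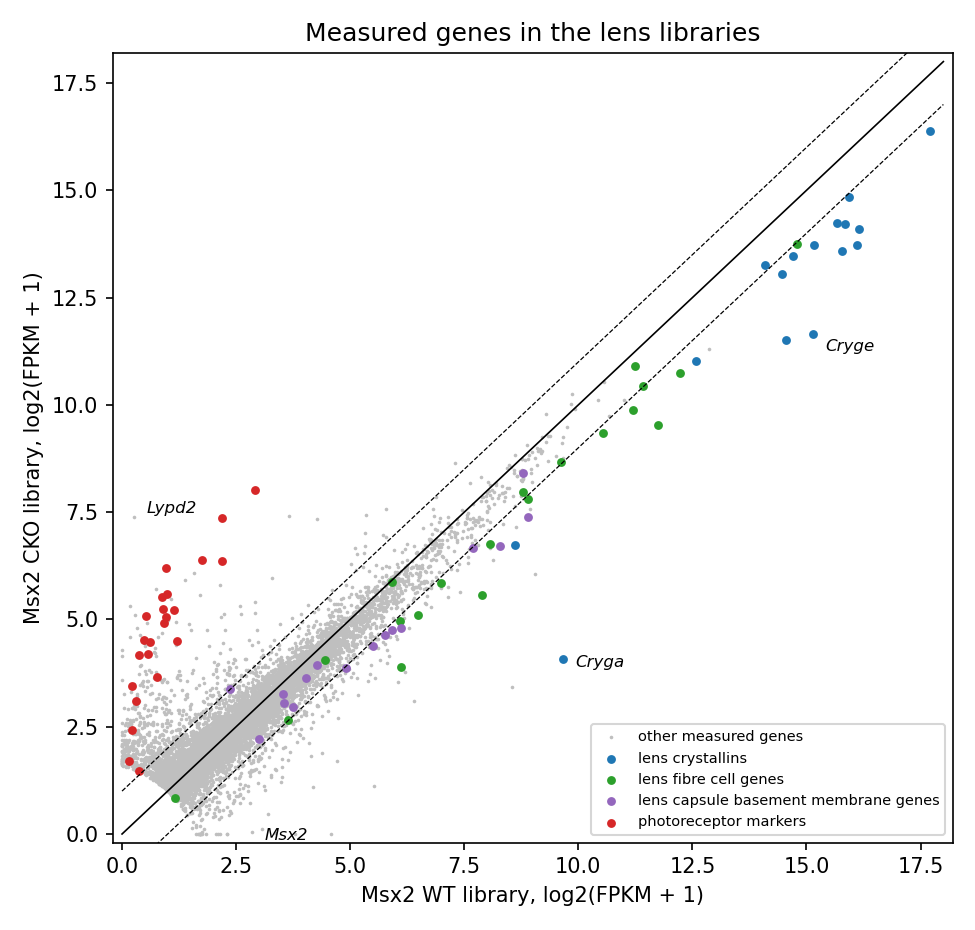
Level of each measured gene in the WT library (x axis) and the CKO library (y axis), both as log2(FPKM + 1), with 1 library per genotype. The solid line marks equal levels and the dashed lines a 2-fold difference. Crystallins (15 of 16 past the size rule) lie below the lines and photoreceptor markers (23 of 23) above.

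Crystallins, the main structural proteins of lens fibres, were lower in CKO in 15 of 16 genes. Their median log2 ratio was -1.58, below all matched random lists (percentile 0, random median -0.27). Under library totals alone the median was -0.69, with 6 genes lower by the size rule (percentile 0). The 15 genes past the rule stayed below 0, as a shift of 0.89 could not bring them across it. Crystallins are far more abundant than the other genes of their expression bin, so the matching is loose for this list. Together they took 40.1% of reads in CKO (40.06 to 40.10) and 61.6% in WT (61.60 to 61.65). The 5 most abundant genes in WT were Cryaa, Crygb, Crygd, Crybb2 and Cryba1. Cryaa was at 85420 FPKM in CKO and 215440 in WT, 2.52-fold lower (2.518 to 2.526). Crybb2 was 2.10-fold lower, Cryba1 3.10-fold lower, Crygb 4.13-fold lower and Crygd 5.23-fold lower. The gamma-crystallins Cryga to Crygf had the lowest ratios of the list: Cryga was 50.8-fold lower (45.0 to 57.6), Cryge 11.1-fold lower (11.04 to 11.24) and Crygf 8.22-fold lower (8.14 to 8.30). Crygd, Cryge and Crygf are similar in sequence, and reads could be divided among them, so their separate values are uncertain. The summed reads of the 6 genes Cryga to Crygf were 5.27-fold lower (5.26 to 5.28), against 2.55-fold for the summed alpha-crystallins and 2.40-fold for 6 beta-crystallins.

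**Figure D2:**
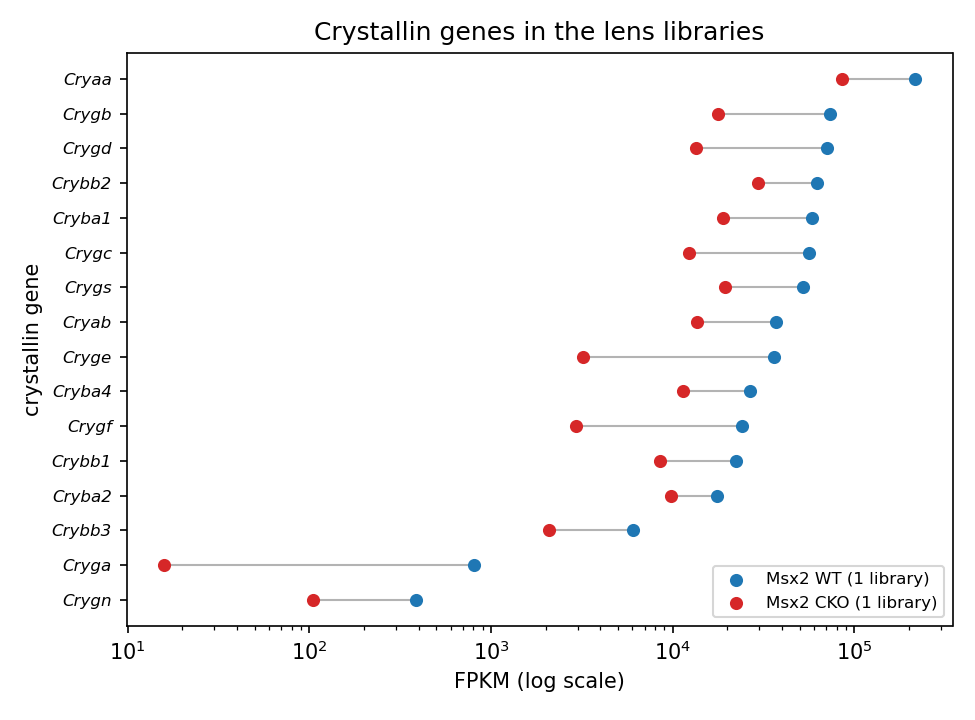
FPKM of the 16 crystallin genes on a log scale in the WT and CKO libraries (1 library each), with a grey line joining the values of each gene. Each gene is lower in CKO, from Cryba2 (log2 ratio -0.84) to Cryga (-5.58), and under library totals alone 1 of the 16 lies above 0.

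Other fibre cell genes were lower too. Of 20 measured, 12 were lower and none higher, and the median log2 ratio of -1.10 lay at percentile 0 of matched random lists. Birc7 was 5.10-fold lower (4.83 to 5.39), Clic5 4.90-fold (4.65 to 5.16), Lgsn, which encodes lengsin, 4.64-fold (4.58 to 4.69), and Bfsp1, which encodes the beaded-filament protein filensin, 2.80-fold (2.77 to 2.82). Under library totals alone the median was -0.22 with 15 of 20 genes below 0 and 3 lower by the size rule (percentile 0). The fibre genes took 3.68% of reads in CKO and 4.62% in WT.

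Genes of the lens capsule, a basement membrane, were lower in 8 of 16 and higher in 1, Agrn, named after its value was seen. The median was -0.91 (percentile 0), and -0.10 under library totals alone with 9 of 16 genes below 0 and none lower by the size rule (percentile 0). The collagen IV genes Col4a2 and Col4a1 were 2.98-fold (2.93 to 3.04) and 2.88-fold (2.84 to 2.92) lower, and Hspg2, which encodes perlecan, was 2.54-fold lower (2.47 to 2.61). Lens epithelial genes had a median of -0.43 (percentile 0.47), with 2 lower, 1 higher and 11 within 2-fold, but the mean did not stand apart (percentile 5.50). Under library totals alone, which lifted all genes, the median was 0.43 at percentile 0.75. The lower genes were Gja1 (connexin 43), 2.96-fold (2.77 to 3.17), and Npnt (nephronectin), 2.88-fold (2.63 to 3.17). The water channel gene Aqp1 was 4.44-fold higher (3.69 to 5.39). Of 24 lens transcription factors 3 were higher and 2 lower, Msx2 itself being 1 of these. Their median of -0.27 lay at percentile 0.77, and was 0.46 at percentile 0.43 under library totals alone. Their mean lay at percentile 12.25, and the median at 14.9 without members shared with other lists. Otx2, also a retinal gene, was at 6.55 FPKM against 0.0964 (520 and 5 reads), 67.9-fold higher (28.9 to 210). Hsf4, a fibre heat-shock factor, was 2.21-fold lower (2.09 to 2.33).

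Signalling lists held few genes past the size rule. Of 17 BMP pathway genes 1 was lower, Smad1, by 2.58-fold (2.28 to 2.92), and of 14 WNT pathway genes 1 was lower, Fzd1, by 2.62-fold (2.36 to 2.91). The list medians of -0.22 and -0.31 lay just below the lower bound, at percentiles 2.02 and 2.36. Under library totals alone they were 0.47 and 0.43, at percentiles 0.66 and 1.24. Neither call held throughout: BMP genes lay at percentile 2.74 with a pseudocount of 0.1 and 2.72 under totals without crystallins, and WNT genes at 2.64 with a minimum of 10 reads and 12.5 under totals without crystallins, their mean at 4.27. Of 13 FGF pathway genes 3 were higher and none lower (percentile 87.5, or 98.98 with a minimum of 10 reads), Fgf2 by 9.12-fold (6.08 to 14.3) and Dusp6, a target of ERK signalling, by 3.55-fold (2.69 to 4.78).

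Cell death and mitotic genes showed little difference by the size rule. Of 26 apoptosis genes 24 lay within 2-fold (percentile 30.7). Fas, a death receptor gene, was 2.91-fold lower (2.54 to 3.34) and the TNF receptor gene Tnfrsf1a 3.34-fold higher (2.48 to 4.57). Of the inflammasome and pyroptosis genes 3 were measured and none passed. Il18 was at 13.8 and 8.16 FPKM, and Nek7 at 7.70 and 8.32. None of 9 measured mitotic genes passed (percentile 4.79), with Pcna at 11.5 and 7.70 FPKM and Mcm7 at 2.24 and 2.87. With a minimum of 10 reads, which kept 30 mitotic genes, that list stood at percentile 0, and it stood at 1.88 under library totals alone and 0.37 under totals without crystallins. Its shift from its random lists was -0.22 by the main rule, -0.25 with 10 reads and -0.75 with 50 reads and 1 added (24 genes, percentile 0). Of 19 G1 regulators and inhibitors of cyclin-dependent kinases 3 were higher and 1 lower, and the list did not stand apart (percentile 65.3). The higher genes were the inhibitors Cdkn2b, by 12.7-fold (7.99 to 21.3), Cdkn1a, by 6.28-fold (4.08 to 10.1), and Cdkn2a, by 8.003-fold (2.93 to 30.5).

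Immediate early genes, transcribed within minutes of a stimulus, were higher in 6 of 16 and lower in none, with a median of 0.59 (percentile 99.99). Ier3 was 30.2-fold higher (13.7 to 82.9) and Klf4 15.9-fold (9.49 to 28.6). Interferon response genes were higher in 4 of 10 and lower in none (median 0.68, percentile 99.98), and those with the largest ratios belong to antigen presentation: the class I genes H2-D1, 9.31-fold (7.82 to 11.2), and B2m, 6.61-fold (5.14 to 8.63). The list's shift from its random lists was 0.67, but 0.15 with a minimum of 10 reads (23 genes, percentile 98.3), 0.41 with 200 reads and 1.08 with 50 reads and 1 added. Leukocyte and macrophage markers were also higher in the CKO library, in 8 of 10 genes with a median of 1.71. All 12 measured mitochondrially encoded genes lay within 2-fold, with a median of 0.32 against -0.18 for matched lists (percentile 100, or 96.9 for the mean). Under library totals alone 11 of the 12 were higher by the size rule, with a median of 1.13. The shift of 0.50 was 0.33 against random lists not matched on level. Their share of reads was 0.764% in CKO and 0.338% in WT, with mt-Co1 at 1222 and 929 FPKM and mt-Cytb at 1033 and 920.

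The following stress, metabolic and matrix lists did not stand apart by the main rule. Of 27 glutathione and antioxidant genes 3 were higher and 3 lower (percentile 96.2, or 98.15 with a minimum of 10 reads and 59.99 against random lists not matched on level). Under library totals alone 11 of them were higher and none lower. The glutathione peroxidase gene Gpx3 was 3.50-fold higher (3.31 to 3.70) and Srxn1 3.45-fold higher (2.81 to 4.26). Hmox1, which encodes haem oxygenase 1, was 2.68-fold lower (2.58 to 2.77) and Gclc 2.70-fold lower (2.55 to 2.85). Of 24 unfolded protein and heat shock genes 3 were higher and none lower (percentile 86.7). They were Chac1, 36.3-fold (9.80 to 303, on 111 and 2 reads), Hspa1b, 6.57-fold (4.14 to 10.98), and Atf4, 2.04-fold (1.89 to 2.202), whose log2 ratio of 1.01 became 0.99 with median-of-ratios scaling, inside 2-fold. Of 20 cholesterol synthesis genes 1 was lower, Dhcr7, by 2.49-fold (2.24 to 2.77), and the list lay at percentile 41.5. Of 21 extracellular matrix and EMT genes 4 were higher and none lower, at percentile 62.6. Tgfbi was 10.8-fold higher (7.50 to 16.2) and Timp1 10.2-fold higher (5.24 to 22.8). With a minimum of 10 reads this list of 34 genes stood at percentile 99.98, and under totals without crystallins at 98.04, but with 200 reads at 45.9. Its shift from its random lists was 0.024 by the main rule and 0.67 with 50 reads and 1 added (29 genes, percentile 100). Ribosomal protein genes lay within 2-fold in 48 of 49 (percentile 82.9, or 0.11 against random lists not matched on level).

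Photoreceptor markers were higher in CKO in all 23 measured genes, with a median log2 ratio of 4.04 (percentile 100) and folds from 6.13 to 77.2. Gnat1 was at 164 FPKM against 3.55, 46.2-fold higher (39.6 to 54.3). Rcvrn was 77.2-fold higher (46.7 to 138) and Nrl 54.2-fold higher (38.3 to 79.4). The photoreceptor markers took 0.540% of reads in CKO (0.536 to 0.543) and 0.00783% in WT (0.00745 to 0.00822). Inner retina and glia markers were higher in 12 of 15 (median 2.02, percentile 100), among them the glial filament gene Gfap, 16.1-fold (12.9 to 20.3), and Calb2, 64.5-fold (21.8 to 314, on 296 and 3 reads). The shift of this second list, 2.02, was 3.64 with a pseudocount of 0.1 and 3.76 with 50 reads and 1 added. These retinal markers differ between the same libraries as every gene group above.

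Leukocyte and macrophage markers were higher in 8 of 10 and lower in 1, H2-Eb1, named after its value was seen (median 1.71, percentile 100). The list's shift of 1.69 from its random lists fell to 0.48 with a minimum of 10 reads, which kept 22 genes (percentile 100). Cd74 was 8.28-fold higher (5.46 to 13.1) and Ctss 9.24-fold higher (5.38 to 17.2). The list's share of reads was 0.0111% in CKO and 0.00166% in WT. Of 7 markers of pigment epithelium, iris and ciliary body 2 were lower, and the median of -0.50 (percentile 0.105) was 0.09 under library totals alone, where the list lay at percentile 1.71. With a minimum of 200 reads the list lay at percentile 59.4. Its shift of -0.50 from random lists was -0.32 with 10 reads, -0.85 with 50 reads and 1 added, and -0.28 under library totals alone. Oca2 was 33.0-fold lower (15.6 to 83.5) and Car14 3.48-fold lower (3.06 to 3.97). Of 7 cornea and conjunctiva markers 1 was higher, Aldh3a1, the aldehyde dehydrogenase abundant in cornea, by 14.5-fold (13.0 to 16.2), and the list lay at percentile 22.6, 99.7 with a minimum of 10 reads and 42.5 with 200. Fewer than 5 genes of the remaining lists were measured. Of 4 endothelial and pericyte markers 1 was higher, Kdr, by 15.8-fold (10.6 to 24.7). The erythroid marker Bpgm was at 7.90 and 10.3 FPKM. Of 2 skeletal muscle markers 1 was lower, Pvalb, by 3.40-fold (1.91 to 6.30).

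**Figure D3:**
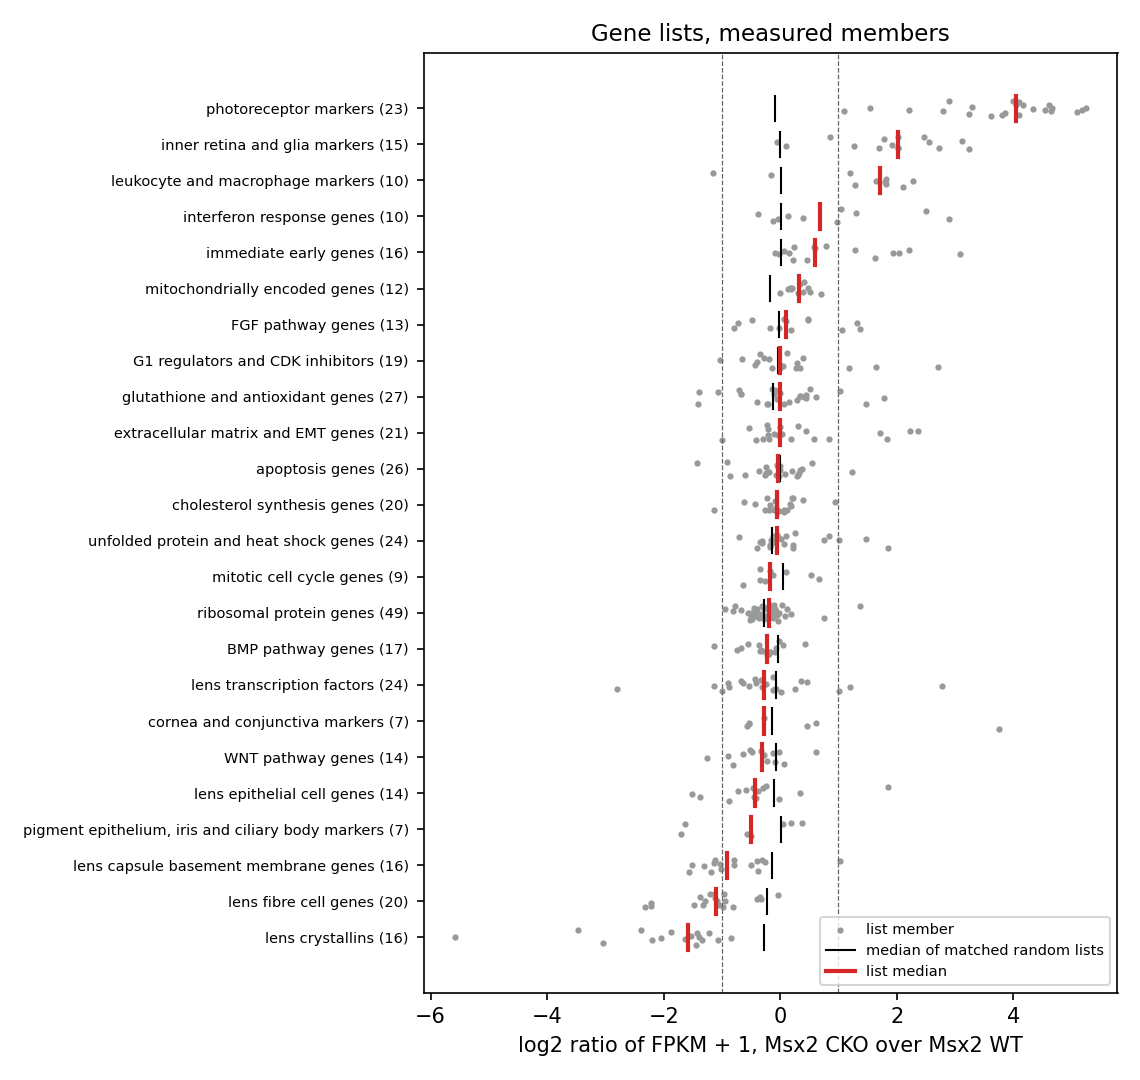
Log2 ratio of FPKM + 1 (CKO over WT, 1 library each) of every measured member of the 24 gene lists with at least 5 measured members, whose number stands in brackets. Red bars mark list medians, black bars the median of 10000 matched random lists, and dashed lines a 2-fold difference. Of the lists, 6 stood above and 8 below the random lists, where 1.2 of 24 would pass if their members varied independently. Members of a list can vary together between any 2 libraries, so 1.2 is not the number to be met by chance for these lists.

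Genes linked to the sex chromosomes also differed. Xist, the RNA that silences an X chromosome in females, had 16251 reads in CKO and 35 in WT, 303-fold higher (218 to 436). The Y-linked gene Eif2s3y had 0 reads in CKO and 819 in WT, 418-fold lower against a floor of 3 reads (lower limit of the counting interval 339). The genes Ddx3y, Uty and Kdm5d, chosen after their values were seen, had 729, 271 and 308 reads in WT and 1, 0 and 0 in CKO. On X and Y together lay 31 of the 942 genes past the size rule (3.29%), and without those chromosomes 607 genes were higher and 304 lower.

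Some of the lowest ratios belong to near-identical gene copies and are uncertain. Rpl34-ps1, a processed pseudogene, was 38.4-fold lower (30.7 to 48.7), while its parent gene Rpl34 was 2.64-fold higher (2.48 to 2.80), the 1 gene of the fixed ribosomal list to pass. Summed over both, CKO was 1.09-fold higher (1.05 to 1.14). Gm4152, another processed pseudogene, had 0 reads in CKO and 90 in WT, 45.9-fold lower against the same floor (lower limit of the counting interval 36.6).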

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

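Settings named here as added were chosen after the data were seen: the count rule, a pseudocount of 0.1, a mean FPKM of 5, protein-coding genes, no X and Y, 50 reads with 1 added, and other scalings of the gene lists. No paired analysis was possible because each genotype has 1 library, and leaving out a library was not possible. The cause of the differences below was not tested, except where fewer or more genes entered by construction.

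The 627 higher genes became 2234 with library totals alone, 1381 with totals without crystallins, 4713 with no minimum and 0.5 reads added, 212 at a fold of 4, 1685 by the count rule and 199 at a mean FPKM of 5. The 315 lower genes became 73, 343, 2361, 36, 483 and 185 in the same order, 512 with 1 read added, 489 with a pseudocount of 0.1 and 204 among protein-coding genes. The log2 ratio of Msx2 was -5.50 with a pseudocount of 0.1, and from -3.57 to -2.40 under other scalings.

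List medians minus the median of their random lists kept their sign and their side of the bounds in 203 of 239 settings. That count includes settings that could hardly differ from the main one, so it does not measure robustness. Leaving out shared members changes nothing in a list that shares none, and other scalings move genes of like level nearly alike. With means, epithelial genes (-0.26), transcription factors (-0.15), WNT genes (-0.29) and mitochondrial genes (0.53) no longer stood apart, nor did transcription factors without shared members (-0.083), BMP genes with a pseudocount of 0.1 (-0.21) or totals without crystallins (-0.19), or WNT genes with 10 reads (-0.13), 50 reads (-0.15), median-of-ratios scaling (-0.22) or totals without crystallins (-0.12). The following stood apart only under other settings: mitotic genes (-0.25 with 10 reads, -0.27 with 200, -0.75 with 50, -0.24 with library totals, -0.36 with totals without crystallins), matrix genes (0.23 with 10, 0.67 with 50, 0.20 with totals without crystallins), FGF genes (0.23 with 10, 0.36 with 50) and antioxidant genes (0.15 with 10). Signs turned for ribosomal genes against unmatched lists (-0.18), pigment epithelium markers with 200 reads (0.032), and cornea markers with 10 reads (0.52), 50 (0.54), the mean (0.57) or totals without crystallins (0.23). Of lists within the bounds under both settings, signs also turned for G1 regulators (-0.042 with 10 reads, -0.023 with library totals), matrix genes (-0.0073 with 200 reads, -0.013 with library totals), unfolded protein genes against unmatched lists (-0.035) and cholesterol genes (0.0093 with 10 reads, 0.020 with library totals, 0.0030 with totals without crystallins). Relative to totals without crystallins, log2 ratios of shares were -0.97 for fibre genes, 5.47 for photoreceptor markers and 0.53 for mitochondrial genes, against -0.33, 6.11 and 1.18.

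Of 94 other named genes, 63 moved beyond their counting interval with library totals alone, 55 with totals without crystallins and 9 with median-of-ratios scaling. Those past the size rule could not change sign, as the largest shift of log2 ratio was 0.89. Of those not past it, 5 changed sign with library totals alone and 1 with totals without crystallins. Of 85 past the rule 20 came within 2-fold with library totals alone, 5 with totals without crystallins and 1, Atf4 (0.99), with median-of-ratios scaling. Depth limits genes with few reads, such as Msx2, Lypd2 and Chac1, whose folds have wide intervals.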

Other observations

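Tests of the scaling of crystallins and fibre genes, dilution, the sex of the animals and reactive glia were chosen after the result was seen. The other tests were written before theirs. Genes named below outside the fixed rule were chosen after their values were seen.

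Part of a reactive glia list, of genes that respond to tissue stress in glia, was higher in the CKO library. Of its 20 measured genes 13 were higher, none lower and 7 within 2-fold, with a median log2 ratio of 1.65. Those within 2-fold included the filament genes Vim (-0.037) and Nes (-0.25). Serpina3n, a serine protease inhibitor gene, was 33.8-fold higher (26.3 to 44.3) and the complement gene C3 31.1-fold higher (24.0 to 41.1). Edn2, which encodes endothelin 2, was 124-fold higher against a floor of 3 reads in WT (lower limit of the counting interval 100). The list was assembled after values of 9 of its 25 genes had been seen, Lcn2, Serpina3n, C3 and Edn2 among them, and 5 of these 9 are in other lists. Without the 9, 6 of 11 measured genes were higher, with a median of 1.37 above every matched random list (percentile 100). Of the whole list 11 genes were at 1 FPKM or more in WT, so lens cells could express part of it, and its cell of origin was not tested. Inner retina and glia markers (12 of 15), photoreceptor markers (23 of 23) and leukocyte markers (8 of 10) were higher in the same library.

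Atf4 and Chac1 passed the size rule, Atf4 not under median-of-ratios scaling (0.99), and Ddit3 was at 10.4 FPKM in CKO and 5.81 in WT. Whether targets of the transcription factor ATF4 were higher as a set was tested on a further list. Its median of 0.25 lay at percentile 99.98, but members went both ways, so whether they moved as a set stays open. Of 23 measured genes 10 were below 0, among them Slc7a5 (-0.89) and Psat1 (-0.62), and 1, Asns, passed the size rule. Asns encodes asparagine synthetase and was 3.47-fold higher (2.32 to 5.35). The other two lists added, further retinal neuron genes and further inner retina interneuron genes, had 22 of 23 and 14 of 17 measured genes higher.

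Retinal genes were higher in CKO. Expression of photoreceptor genes alone in lens cells is argued against by the interneuron genes. Their median log2 ratio was 3.94 (bootstrap 95% interval 3.15 to 4.66 over 28 genes, 1 read added). The interval leaves out that these genes can vary together between 2 libraries. The interneuron list was also written after inner retina and glia markers had been seen to be higher (12 of 15). On FPKM + 1, as for the other lists, the interneuron median was 1.90 over 17 measured genes, against 4.04 for photoreceptor markers. Of 26 further retinal neuron genes 4 were at 1 FPKM or more in WT, among them Eml1, which was 1.21-fold higher in CKO. Of the 26, 96.2% were at least 2-fold higher, as retinal tissue or RNA in the CKO sample could give. Many of the 26 are photoreceptor genes, and photoreceptor markers had already been seen to be higher. This share therefore cannot tell retinal material from photoreceptor genes expressed in lens cells. Whether such material was present, and if so came with dissection or adhered to a lens altered by the loss of Msx2, stays open, since a wider set of retinal genes expressed by CKO lens cells was not tested.

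Crystallin and fibre genes were lower in CKO. Scaling is argued against as the whole cause for crystallins, whose share of unscaled reads was lower by 21.5 percentage points, and for fibre genes, whose shift from random lists of like level was -0.88 (bootstrap 95% interval -1.08 to -0.73), or -0.89 under library totals alone, although their median went from -1.10 to -0.22. Dilution of lens RNA by other cells would lower crystallins by a common factor, and is argued against as the only cause for Cryga to Crygf, since the log2 ratio of their summed reads minus that of the other 10 was -1.09 (-1.090 to -1.080), but stays open for those 10, whose log2 ratios had an SD of 0.29. Loss of short transcripts is argued against for abundant protein-coding genes by 72 short ones outside the lens lists, with a median log2 ratio of -0.21 (bootstrap 95% interval -0.30 to -0.14). That test left out other gene types, of which 12.1% were lower and 6.98% higher, against 2.07% and 5.72% of protein-coding genes. Some of the lowest ratios belong to short genes of those types, such as Gm4152 (259 bases), Rn7sk (331) and Rpl34-ps1 (354). Loss of short transcripts stays open for them. Loss of Msx2, the Cre transgene and differences between animals stay open as explanations and were not tested.

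The libraries likely came from animals of different sex. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had a level in CKO of 0.0307% of that in WT, and Xist was 303-fold higher. Genes on X and Y made up 3.29% of the genes past the size rule, so most differing genes lay on other chromosomes. That outcome was fixed in advance. Of 10757 measured genes 334 lay on X and 4 on Y, too few to make up most of the 942 past the rule. Effects of sex on other chromosomes cannot be separated from genotype here, since sex and genotype differ together.

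The ribosomal protein gene Rpl29, outside the fixed list, was 8.02-fold lower in CKO (7.54 to 8.53), and no copy of it was examined. The processed pseudogene Rpl3-ps1 was 5.68-fold lower (5.05 to 6.40) while Rpl3, at a ratio of 1.70 (1.64 to 1.75), did not pass the size rule, and their sum was 1.39-fold higher (1.35 to 1.43).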
